A study of Homo sapiens with 6 samples.

How the data were processed

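Raw counts per gene were analysed as deposited, 1 column per library. Per the labels, MDA-MB-231 cells were transfected with an esiRNA against CDYL2 or against luciferase, RNA was taken at 72 h with TRI-reagent, and libraries were made with the TruSeq Stranded Total RNA kit. The submitters' processing notes name STAR 2.7.0f, R 3.4.4, DESeq2 1.14 and the build hg38 without saying what each did, and the counting program and its strand setting are not given in the sources used here. The counts were whole numbers and were used without any change before scaling.

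All 58721 gene IDs of the count tables matched GENCODE 29, 45 of them copies in the pseudoautosomal regions of the Y chromosome. Gene symbols, positions, types, exonic lengths and sequences were taken from that release. Of 857 list symbols, 3 had no gene in the counts (LINC00600, H3C2 and H3C3). Each of the 6 columns was assigned to a library by its label, and 0 columns were left unassigned.

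Genes were kept by filterByExpr of edgeR with its default minimum count of 10, which left 15407 for testing, 12529 of them protein coding. Library sizes were scaled by TMM, with factors from 0.987 to 1.02. siCDYL2 was compared with siLuc by the edgeR quasi-likelihood test with robust dispersion (3 against 3 libraries), and p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Log2 fold changes are fitted values of edgeR with its default shrinkage, CPM values are scaled counts, and the list tests used log2 CPM with a prior count of 2. Changed genes were counted as higher, lower and at least 2-fold changed. Sampling noise alone would give a mean chi-square of 1 per gene between replicates of a group, and the observed means ran from 1.96 to 6.06. Correlation of log levels was 0.995 to 0.996 within groups and 0.992 to 0.995 between them, and the first principal component (43.3% of variance) separated the groups.

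28 gene lists were written down before the data were examined, as were the comparison, the tests, the thresholds, the rule for named genes and all alternatives except those stated to have been added later. The lists hold the CDY family, complexes of H3K9 and H3K27 methylation, miR-124 host genes and reported targets, NF-kB and STAT3 components and the targets of each, mesenchymal, epithelial, invasion, stem cell, luminal and basal markers, interferon response, G1/S, G2/M, replication-dependent histones, p53 targets, unfolded protein and integrated stress response, cholesterol synthesis, hypoxia and glycolysis, TGF-beta and YAP targets, immediate early genes, RNA interference machinery, mitochondrially encoded transcripts, cytosolic ribosomal proteins, and blood and endothelial cell markers. They were compiled from general knowledge of the field. The 25 with at least 5 tested members were tested with limma camera at the preset correlation of 0.01 and adjusted by Benjamini-Hochberg, and again with an estimated correlation and with fry.

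The genes named by rule were CDYL2, CDYL, RELA, NFKB1, STAT3, IL6, VIM, CDH1 and the miR-124 host genes, the 10 largest changed genes in each direction with a mean of at least 5 CPM, groups that did not overlap and a symbol that is neither clone-based nor of a pseudogene, and, among members past the test, up to 4 with the smallest p from each list tied to the question or past the list test and up to 2 from every other list. Every other gene named was picked after its value was seen.

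Replicate numbers are shared by the groups in the labels, and no statement there pairs the libraries, so the comparison was unpaired. Alternatives were the DESeq2 Wald test, limma-voom, upper-quartile scaling, the median-ratio size factors of DESeq2, scaling without the 10 most abundant genes, no filter, a stricter filter (1 CPM in 3 libraries), a block term, and each library left out in turn. A smooth correction per library for exonic length and GC content was added after the data were seen.

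The procedure was tried on counts simulated for this comparison from the mean levels, depths and gene-wise dispersions of the 6 libraries, with 200 of 15407 genes changed. The changed genes were drawn from those with a mean of at least 1 CPM. Recovery was therefore not measured below that level, where many of the 2-fold calls in the data lie. It recovered 64.2% of 67 genes changed 1.25-fold, 83.6% of 67 changed 1.5-fold and 95.5% of 66 changed 2-fold. Of 174 calls 12 were false (6.90%), a share above the threshold set for the adjusted p. In the data 3865 genes were called changed, and 2751 of them were under 1.25-fold. No smaller change was simulated, so the trial does not measure recovery at the size of most calls. It also changed a smaller share of genes than was called in the data, so its false-call share may not carry over. The list test found the 1 list shifted by 1.25-fold and called 0 others. Simulated genes varied independently, so this trial does not measure false calls among lists whose members move together. A 7-base word whose carriers were lowered by 0.1 was estimated at -0.0991 and ranked 1 of 16384.

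Sites for the miR-124 seed and other 7-base words were counted in the longest annotated 3' UTR of each coding gene, where it had at least 50 bases. Matches to the coding sequence of CDYL2 stood in for the esiRNA, whose own sequence was not used here. Levels of the Y-linked CDY genes are not reported here. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.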

Results

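RNA was measured in MDA-MB-231 cells, a mesenchymal-like, triple-negative line of human breast cancer, 72 h after transfection with an esiRNA. An esiRNA is a pool of short RNA duplexes cut enzymatically from a long double-stranded RNA. The pool was directed against CDYL2 in 3 libraries (siCDYL2) and against luciferase, which human cells lack, in 3 control libraries (siLuc). CDYL2 is a chromodomain protein related to the testis-specific CDY proteins of the Y chromosome. Per the labels the libraries were made from total RNA with a strand-specific kit. Their gene counts summed to 27625398, 29353680 and 28938206 in siLuc replicates 1 to 3 and to 26986167, 27504875 and 30686748 in siCDYL2 replicates 1 to 3. The mitochondrial ribosomal RNA MT-RNR2 took 13% to 15% of the counts of each library. Levels below are CPM, TMM-scaled counts per 1000000, given as mean ± SD of 3 libraries per group. The labels number the replicates without saying that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The strand setting of the counting is not given in the sources used here, so antisense genes are uncertain, as are genes that share reads with near-identical copies, such as histones, ribosomal proteins, protocadherins and NPIPB5.

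The targeted transcript fell in every siCDYL2 library. CDYL2 (ENSG00000166446, chromosome 16, 80597906 to 80804329 on the minus strand of hg38) stood at 57.8, 58.5 and 59.7 CPM in siLuc replicates 1 to 3 and at 10.6, 10.6 and 10.8 CPM in siCDYL2 replicates 1 to 3. The fitted log2 fold change was -2.46 (SE 0.0531, n = 3 per group), which leaves 18.2% of the siLuc level, with an edgeR quasi-likelihood adjusted p of 2.53e-18. Its paralog CDYL, a corepressor that binds methylated histone H3 (chromosome 6, 4706159 to 4955551), fell from 63.8 ± 2.02 to 52.1 ± 0.232 CPM (log2 fold change -0.29, SE 0.0417, edgeR adjusted p = 2.90e-05). These were the 2 members of the CDY list that entered the test, and both stayed past it when adjusted over the list alone. The Y-linked members were not used here. Of the 12 genes tested that lie in or within 1000000 bp of CDYL2, CDYL2 was the 1 that changed by edgeR. CMC2 and CENPN, to its right on the chromosome, had log2 fold changes of 0.08 and 0.03.

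Genes of the complexes that place or read methylation on lysines 9 and 27 of histone H3 moved both ways by small amounts. Of 28 tested, 5 rose, 4 fell and 19 did not pass the edgeR test, with the same 5 and 4 when adjusted over the list alone. RBBP7, a histone-binding subunit of Polycomb repressive complex 2, rose by 0.32 on the log2 scale to 126 ± 3.80 CPM, and CBX3, a heterochromatin protein, from 88.9 ± 0.694 to 105 ± 5.34 CPM. The other rises were PHF19, EZH2 and MIER1 (log2 fold changes 0.22, 0.25 and 0.14), and the falls were CBX5, JARID2, EZH1 and SUZ12 (-0.16, -0.18, -0.18 and -0.13). These 7 were named after their values were seen, as were all other members named below to spell out a count of 5 or fewer, and the calls of MIER1 and SUZ12 were lost in 7 of 15 alternative settings. The list as a whole did not stand apart from other genes (limma camera adjusted p = 0.801), and its median (-0.03) and mean (0.00) were near 0.

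**Figure D1:**
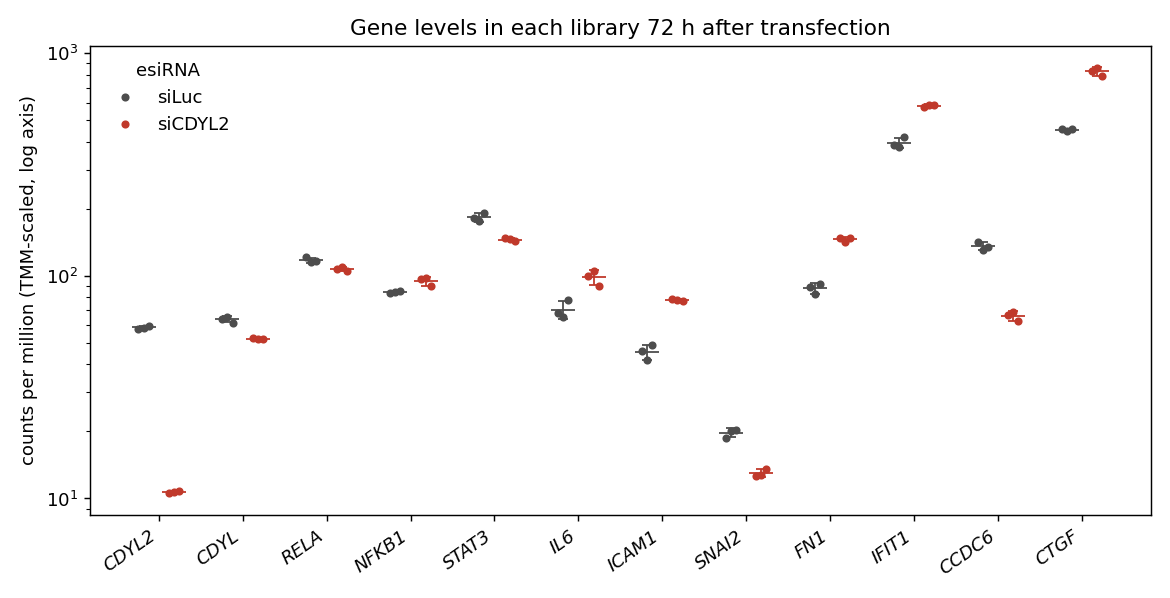
CPM (log axis) of 12 genes in each of the 6 libraries, grey for siLuc and red for siCDYL2, with dots for libraries, horizontal bars for group means and error bars for SD (n = 3). CDYL2 lies at 57.8 to 59.7 CPM in siLuc and at 10.6 to 10.8 CPM in siCDYL2, while RELA and NFKB1 shift by little (log2 fold changes -0.13 and 0.16).

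The series title links CDYL2 to MIR124, so the host transcripts and the reported targets of this microRNA were examined next. The genes MIR124-1, MIR124-2 and MIR124-3 and the host transcripts LINC00599 and MIR124-2HG had 0 counts in all 6 libraries. A count of 0 allows up to 0.0978 to 0.111 CPM per library (3 counts, counting error only), and libraries of this kind capture mature microRNAs poorly, so no change of MIR124 was detectable at this depth. The list of reported miR-124 targets was compiled from general knowledge and shares members with other lists. Of its 38 tested genes, 17 fell, 3 rose and 18 did not pass the edgeR test (17 and 4 adjusted over the list alone). NRP1, a semaphorin and VEGF co-receptor, fell from 164 ± 2.74 to 108 ± 3.64 CPM (log2 fold change -0.60), and SNAI2, a transcription factor of the epithelial-mesenchymal transition, by the same amount from 19.8 ± 0.889 CPM (-0.60). STAT3 and IL6R, the alpha chain of the IL-6 receptor, fell by 0.33 and 0.48 on the log2 scale. The rises were JAG1, EZH2 and ROCK2 (log2 fold changes 0.19, 0.25 and 0.12), of which EZH2 was lost without siCDYL2 replicate 2 and ROCK2 without siLuc replicate 2 or siCDYL2 replicate 1. The list lay below other genes with a median log2 fold change of -0.10 (camera adjusted p = 0.00354 with the preset correlation). That call was lost at an adjusted p = 0.756 with an estimated correlation and held in 14 of 15 alternative settings.

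The genes of the NF-kB and STAT3 pathways were split in direction. STAT3 (chromosome 17, 42313324 to 42388568) fell from 183 ± 8.0 to 146 ± 2.52 CPM (log2 fold change -0.33, SE 0.0368, edgeR adjusted p = 1.29e-06), and RELA, the p65 subunit of NF-kB (chromosome 11, 65653596 to 65663094), from 118 ± 3.23 to 107 ± 2.71 CPM (-0.13, SE 0.0368, edgeR adjusted p = 0.0120). NFKB1 (chromosome 4, 102501329 to 102617302) rose from 84.5 ± 1.08 to 94.8 ± 4.46 CPM (0.16, SE 0.0400, edgeR adjusted p = 0.00421). IL6, a target of NF-kB and an activator of STAT3 (chromosome 7, 22725884 to 22732002), rose from 70.4 ± 6.57 to 98.4 ± 7.56 CPM (0.48, SE 0.0724, edgeR adjusted p = 0.00109). The RELA call was lost without siLuc replicate 1 (edgeR adjusted p = 0.103), without siCDYL2 replicate 1 (0.0513) and with the replicate block (0.0518).

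Among 33 tested pathway components, 9 rose, 10 fell and 14 did not pass the edgeR test (10 and 10 adjusted over the list alone). IKBKE, a kinase upstream of NF-kB and interferon regulatory factors, rose to 27.8 ± 1.12 CPM (log2 fold change 0.55), and NFKB2 rose by 0.25. SOCS3, a feedback inhibitor of STAT3 signalling, fell from 74.2 ± 0.651 to 56.7 ± 1.27 CPM (-0.39). The component list had a median log2 fold change of 0.02 and did not stand apart (camera adjusted p = 0.946). NF-kB target genes rose more often than they fell, with 15 of 34 rising, 5 falling and 14 not past the edgeR test (18 and 5 adjusted over the list alone). ICAM1, an adhesion molecule for leukocytes, rose from 45.6 ± 3.59 to 77.9 ± 0.656 CPM (0.77). CD83 rose by 0.51 and BIRC3, an inhibitor of apoptosis, by 0.33. The cytokine gene LIF fell from 365 ± 6.14 to 259 ± 2.28 CPM (-0.49), as did IL1B (-0.59), BCL3 (-0.44), CSF3 (-0.31) and CXCL1 (-0.15). The BCL3 call was lost without siLuc replicate 2 and that of CXCL1 without siLuc replicate 1 or siCDYL2 replicate 1. The list's median was 0.12 (camera adjusted p = 0.0388, and adjusted p = 0.756 with an estimated correlation). That call also ended without siLuc replicate 2 (camera adjusted p = 0.0846), without siCDYL2 replicate 1 (0.0815) and without siCDYL2 replicate 3 (0.0504). It ended with the replicate block as well (camera adjusted p = 0.0668).

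STAT3 target genes fell more often than they rose, with 12 of 29 falling, 6 rising and 11 not past the edgeR test (13 and 6 adjusted over the list alone). LIF, SOCS3 and HIF1A, the oxygen-regulated transcription factor subunit, fell by 0.49, 0.39 and 0.33 on the log2 scale. ICAM1, which is on both target lists, was the member with the smallest p and rose. The median was -0.11 (camera adjusted p = 0.0456, and adjusted p = 0.756 with an estimated correlation). Leaving out any library but siLuc replicate 3 ended this call, and it held in 6 of 15 alternative settings (camera or fry adjusted p from 0.0223 to 0.756).

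Markers of the mesenchymal state, which MDA-MB-231 cells show from the outset, rose more often than they fell. Of 27 tested, 11 rose, 3 fell and 13 did not pass the edgeR test (11 and 4 adjusted over the list alone). The matrix protein gene FN1 rose from 88.0 ± 4.65 to 146 ± 2.87 CPM (log2 fold change 0.73, edgeR adjusted p = 5.19e-11), SPARC from 18.8 ± 1.56 to 28.0 ± 1.67 CPM (0.57) and the hyaluronan receptor gene CD44 from 284 ± 2.49 to 339 ± 5.61 CPM (0.25). The falls included SNAI2 (-0.60) and ZEB1 (-0.27), which encode transcriptional repressors of epithelial genes. VIM, the intermediate filament of mesenchymal cells, averaged 3025 CPM in siLuc and 3206 CPM in siCDYL2, and the groups overlapped. Its log2 fold change of 0.08 was not past the edgeR test (adjusted p = 0.124) and was past it without siCDYL2 replicate 3 (0.00657) and with upper-quartile scaling (0.0499). The mesenchymal list had a median of 0.11 and did not stand apart (camera adjusted p = 0.192).

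Epithelial genes were expressed at low levels, and 14 of 20 tested did not pass the edgeR test. CLDN4, a tight junction protein gene, rose from 1.51 ± 0.116 to 2.51 ± 0.353 CPM (log2 fold change 0.73), and JUP, KRT7 and LLGL2 rose by 0.26, 0.29 and 0.35. The desmosomal genes DSP and PKP3 fell by 0.38 and 0.15. Adjusted over the list alone, 6 rose and 3 fell. JUP missed the threshold without siCDYL2 replicate 1 (edgeR adjusted p = 0.0502), while the PKP3 and LLGL2 calls were lost in 8 and 5 of 15 alternative settings. CDH1, which encodes E-cadherin, had 2, 3 and 2 counts in siLuc and 2, 2 and 4 counts in siCDYL2, too few for a test. The list did not stand apart (camera adjusted p = 0.601).

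Genes of invasion and extracellular proteolysis were divided, with 12 of 34 rising, 8 falling and 14 not past the edgeR test (15 and 10 adjusted over the list alone). The collagenase gene MMP1 fell from 61.7 ± 2.96 to 44.2 ± 2.75 CPM (log2 fold change -0.48), whereas the gelatinase gene MMP9 rose from 47.4 ± 0.288 to 62.1 ± 5.53 CPM (0.39). SPARC and the integrin gene ITGAV rose by 0.57 and 0.26. The list did not stand apart (camera adjusted p = 0.601). Among 21 tested genes associated with stem cells, 4 fell, 2 rose and 15 did not pass, with the same counts adjusted over the list alone. NOTCH2 fell from 612 ± 27.1 to 485 ± 32.3 CPM (-0.34), and SOX9, ALDH1A3 and MYC fell by 0.35, 0.23 and 0.11. The MYC call was lost without siLuc replicate 1 and with the replicate block. CD44 and the Notch ligand gene JAG1 were the rises (camera adjusted p for the list = 0.487).

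Luminal markers of the breast changed in few members and basal markers in both directions. Of 15 tested luminal genes, PRLR and MLPH rose (log2 fold changes 0.43 and 0.72), GREB1, an estrogen-responsive gene at 3.45 ± 0.324 CPM in siLuc, fell by 0.79, and 12 did not pass, with the same counts adjusted over the list alone. The MLPH call was lost without siLuc replicate 2 (edgeR adjusted p = 0.0907) and without siCDYL2 replicate 2 (0.0717). The luminal median (-0.00) and mean (0.01) were near 0 with opposite signs (camera adjusted p = 0.801). Of 15 tested basal or myoepithelial genes, KRT17, ITGB4 and MYLK rose (0.84, 0.61 and 0.54), EGFR, S100A2, FOXC1, LAMB3 and SFN fell (-0.30, -0.41, -0.30, -0.20 and -0.17), and 7 did not pass (3 and 6 adjusted over the list alone). EGFR, the epidermal growth factor receptor gene, went from 213 ± 1.95 to 173 ± 1.67 CPM. The basal median was -0.11 and the mean 0.04, and the list did not stand apart (camera adjusted p = 0.601).

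Across the transcriptome, changes were many and small. Of 15407 genes tested, 3865 changed, 1782 of them higher and 2083 lower in siCDYL2, at a median absolute log2 fold change of 0.23 (1.18-fold). The change was at least 1.5-fold in 317 of them and at least 2-fold in 79, of which 70 rose and 9 fell. The 2-fold count depended on the test and the filter, at 17 with DESeq2, 127 without a filter on low counts and 21 with a stricter filter. Among genes above a mean of 5 CPM over the 6 libraries, the largest rise was that of MATN2, an extracellular matrix gene, by 2.38-fold from 5.48 ± 0.736 CPM (SE on the log2 scale 0.115). It was followed by FST, the activin antagonist follistatin (log2 fold change 1.09), the cathepsin gene CTSV (1.04), the Wnt receptor gene ROR1 (0.93), the protocadherin gene PCDH7 (0.92), PBXIP1 (0.92), SLCO4C1 (0.89), the angiopoietin gene ANGPT2 (0.89), CTGF (0.88) and TSPAN15 (0.84). CTGF, a target of TGF-beta and YAP signalling, was the most abundant of these and rose from 452 ± 5.51 to 830 ± 36.2 CPM (edgeR adjusted p = 2.65e-13). With the same limit of 5 CPM, the largest fall after CDYL2 was that of CCDC6, from 136 ± 5.67 to 66.1 ± 3.16 CPM (-1.04, SE 0.0423, edgeR adjusted p = 3.51e-13). RAB11FIP5, an effector of endosome recycling, fell from 66.4 ± 3.46 to 34.5 ± 1.32 CPM (-0.94), and the RNA-binding protein gene RBMS1 from 119 ± 1.88 to 66.7 ± 1.78 CPM (-0.83). The remaining largest falls were SERPINB2 (-0.89), S1PR1 (-0.80), TGFA (-0.71), the tenascin gene TNC (-0.71), the cyclin gene CCND2 (-0.71) and JAZF1 (-0.69).

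These counts come from the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, against a biological coefficient of variation of 0.0363. The groups did not overlap in 6086 genes, where chance gives 10%. Upper-quartile scaling, which shifted the median log2 fold change by 0.02, turned the split to 2247 higher and 1707 lower (56.8% higher, against 46.1% with TMM scaling), so the balance of rises and falls depends on the scaling. Without siLuc replicate 1 the counts were 2571 changed and 1133 higher, and without siLuc replicate 2 the number higher was 1159.

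**Figure D2:**
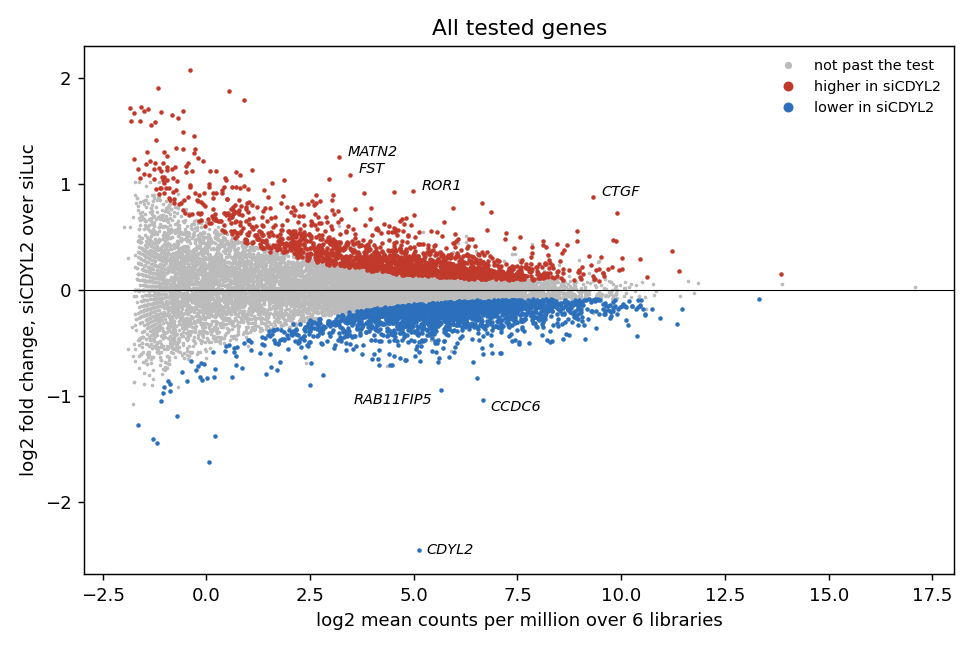
Log2 fold change (siCDYL2 over siLuc, 3 libraries each) of 15407 tested genes against log2 mean CPM over the 6 libraries, with red and blue dots for genes higher and lower by the edgeR test and grey dots for the rest. CDYL2, at -2.46, lies apart from all other genes of its abundance, and 317 of the 3865 coloured dots lie at or beyond 1.5-fold.

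Genes of the interferon response rose far more often than they fell. Of 38 tested, 21 rose, 1 fell and 16 did not pass the edgeR test (27 and 1 adjusted over the list alone), with a median log2 fold change of 0.25. The antiviral effector gene IFIT1 rose from 396 ± 22.0 to 582 ± 6.85 CPM (0.56, edgeR adjusted p = 1.05e-09), IFIT2 from 2073 ± 33.7 to 2672 ± 140 CPM (0.37), HERC5, the ligase that attaches ISG15, from 123 ± 3.19 to 171 ± 9.61 CPM (0.48) and the lambda interferon gene IFNL1 from 41.7 ± 3.24 to 65.1 ± 2.23 CPM (0.64). IRF7 fell from 8.79 to 7.10 CPM (-0.31), a call lost in 3 of 15 alternative settings. The list stood above other genes (camera adjusted p = 8.68e-08, and adjusted p = 0.756 with an estimated correlation). All other alternative settings kept the call.

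Genes of the RNA interference machinery fell more often than they rose. Of 15 tested, 8 fell, 1 rose and 6 did not pass the edgeR test (9 and 1 adjusted over the list alone). TNRC6C, a scaffold of the silencing complex, fell from 34.3 ± 2.51 to 21.6 ± 2.12 CPM (log2 fold change -0.67), and AGO1, DICER1 and TNRC6A fell by 0.35, 0.22 and 0.18. The rise was TSNAX (0.21), lost without siLuc replicate 1. The median was -0.13 (camera adjusted p = 0.0456, and adjusted p = 0.756 with an estimated correlation). Leaving out any of the 6 libraries ended this call (camera adjusted p from 0.0504 to 0.0815).

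Genes of the unfolded protein and integrated stress responses fell more often than they rose. Of 33 tested, 13 fell, 3 rose and 17 did not pass the edgeR test, with the same 13 and 3 adjusted over the list alone. EDEM1, which directs misfolded glycoproteins to degradation, fell from 313 ± 16 to 233 ± 3.12 CPM (log2 fold change -0.43), the chaperone gene PDIA4 from 141 ± 2.41 to 111 ± 1.46 CPM (-0.34) and the phosphatase subunit gene PPP1R15A by 0.23. The rises were the cystine transporter gene SLC7A11 (0.22) and the transcription factor genes DDIT3 (0.27) and ATF3 (0.17). The median was -0.09 (camera adjusted p = 0.0266, and adjusted p = 0.756 with an estimated correlation), and all other alternative settings kept the call.

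Replication-dependent histone genes rose in 10 of 28 tested members and fell in none by edgeR, with 18 not past the test and 10 past it when adjusted over the list alone. The linker histone gene HIST1H1E rose from 788 ± 62.5 to 1084 ± 72.9 CPM (log2 fold change 0.46), and HIST1H3A, HIST1H2AJ and HIST1H2BD rose by 0.22, 0.17 and 0.16. The HIST1H2AJ values of the groups overlapped, and its call was lost in 5 of 15 alternative settings, those of HIST1H2BD and HIST1H3A in 3 and 2. Histone genes share sequence, so reads may be divided among copies, and single members are uncertain. The median was 0.24 (camera adjusted p = 5.59e-04, adjusted p = 0.767 with an estimated correlation, and fry adjusted p = 0.0812).

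Genes of the cell cycle showed little common shift as lists. Of 38 tested genes of G1/S and DNA replication, 6 rose and 6 fell (6 and 7 adjusted over the list alone), with UHRF1, which recruits the maintenance DNA methyltransferase, falling to 37.5 ± 1.77 CPM (log2 fold change -0.50) and RRM2 by 0.32. Of 39 tested genes of G2/M and mitosis, 11 fell and 2 rose (11 and 3 adjusted over the list alone). ANLN, a scaffold of the cytokinetic ring, fell from 165 ± 1.23 to 109 ± 1.27 CPM (-0.60) and UBE2C from 182 ± 4.96 to 135 ± 8.76 CPM (-0.43), while BUB1 and NDC80 rose by 0.13 and 0.12, calls lost in 5 and 8 of 15 alternative settings. The camera adjusted p was 0.946 for G1/S and 0.340 for G2/M. Relative to the siLuc mean, the mean log2 level of the G1/S list was 0.0234, 0.177 and -0.0917 in siCDYL2 replicates 1 to 3. In siLuc it ran from -0.0191 to 0.0188, so the siCDYL2 replicates differed in direction. Among 27 tested p53 target genes, 6 fell and 4 rose (8 and 5 adjusted over the list alone). AEN fell by 0.25, and the rises were BBC3, from 34.6 ± 1.32 to 46.3 ± 1.16 CPM (0.42), CCNG1 (0.44), TNFRSF10B (0.24) and FDXR (0.71). The p53 median was -0.07 and the mean 0.01 (camera adjusted p = 0.742).

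Targets of TGF-beta and YAP and immediate early genes moved in both directions. Of 32 tested TGF-beta and YAP targets, 11 rose and 9 fell (11 and 10 adjusted over the list alone), led by CTGF and by FSTL1, from 157 ± 6.03 to 221 ± 9.73 CPM (log2 fold change 0.50, camera adjusted p for the list = 0.601). Of 31 tested immediate early genes, 12 fell and 5 rose (12 and 8 adjusted over the list alone). EGR1 rose from 237 ± 11.5 to 319 ± 17.6 CPM (0.43), followed by CYR61 (0.23), ATF3 (0.17), FOS (0.16) and DUSP6 (0.13), and SRF, a regulator of the class, fell by 0.34 (camera adjusted p for the list = 0.507). The calls of FOS and DUSP6 were lost in 4 and 5 of 15 alternative settings.

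Among metabolic genes, 5 of 31 tested genes of cholesterol and lipid synthesis rose and 2 fell, with the same counts adjusted over the list alone. INSIG1, a sterol-regulated brake on this pathway, rose from 30.4 ± 1.31 to 41.2 ± 4.78 CPM (log2 fold change 0.44), and FDFT1, EBP and STARD4 rose by 0.34, 0.22 and 0.16. ACACA fell by 0.14, and the calls of FDFT1, STARD4, EBP and ACACA were lost in 4, 5, 6 and 7 of 15 alternative settings. The median was 0.12 (camera adjusted p = 0.0388, and adjusted p = 0.799 with an estimated correlation). Relative to the siLuc mean, the list's mean log2 level was 0.148, 0.223 and 0.0287 in siCDYL2 replicates 1 to 3. The value of siCDYL2 replicate 3 lay below that of siLuc replicate 3 (0.0408). The call ended with fry (adjusted p = 0.194) and without siLuc replicate 2, siCDYL2 replicate 1 or siCDYL2 replicate 2 (camera adjusted p = 0.0846, 0.0815 and 0.149). It ended with the replicate block as well (camera adjusted p = 0.0668). Of 32 tested genes of hypoxia and glycolysis, 6 rose and 7 fell (7 and 8 adjusted over the list alone). The mitophagy receptor gene BNIP3L rose by 0.33 and the hexokinase gene HK2 fell by 0.35, and the list's median (-0.04) and mean (0.02) had opposite signs (camera adjusted p = 0.946).

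Most cytosolic ribosomal protein genes did not pass the edgeR test, with 19 of 66 falling by small amounts, 5 rising and 42 not past it (21 and 5 adjusted over the list alone). RPL10A went from 930 ± 4.35 to 805 ± 26.0 CPM (log2 fold change -0.21), and RPL12, RPL6 and RPS2 fell by 0.18, 0.16 and 0.15. RPL18, RPS9, RPS28, RPL4 and RPL29 rose by 0.11 to 0.17, the last 3 with calls lost in 2, 4 and 6 of 15 alternative settings. The median was -0.05 (camera adjusted p = 0.0456, and adjusted p = 0.756 with an estimated correlation). The call held in 6 of 15 alternative settings and was lost with upper-quartile scaling (camera adjusted p = 0.139) and without siLuc replicate 2, siLuc replicate 3, siCDYL2 replicate 1 or siCDYL2 replicate 2. Of the 15 mitochondrially encoded transcripts, MT-CO3 rose (0.18) and the other 14 did not pass, also when adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.946).

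Markers of other cell types gave no common shift. Of the blood cell list, 3 genes were tested, and LCP1, which tumour lines can also express, fell from 588 ± 31.1 to 478 ± 13.7 CPM (log2 fold change -0.30) and was the 1 past the edgeR test, also when adjusted over the list alone. Of 6 tested endothelial genes, EGFL7 rose by 0.25 and CDH5, at 0.305 CPM in siLuc, by 1.07 (2 rises and 1 fall adjusted over the list alone). The CDH5 call was lost in 4 of the 13 alternative settings that tested it, and the endothelial list, with a median of -0.00 and a mean of 0.19, did not stand apart (camera adjusted p = 0.630).

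Of 25 lists with at least 5 tested members, 9 passed limma camera with its preset correlation of 0.01, 4 upward and 5 downward. With an estimated correlation 0 passed. Mixed groupings of the 6 libraries, described at the end, passed 1 to 5 lists with the preset correlation. The self-contained test fry called 9 lists as moving on balance one way, 7 of them shared with camera, and 24 as changing in either direction. This test does not compare a list with other genes. With 3865 of 15407 tested genes changed, most lists would pass it in either direction, so the 24 do not set lists apart.

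**Figure D3:**
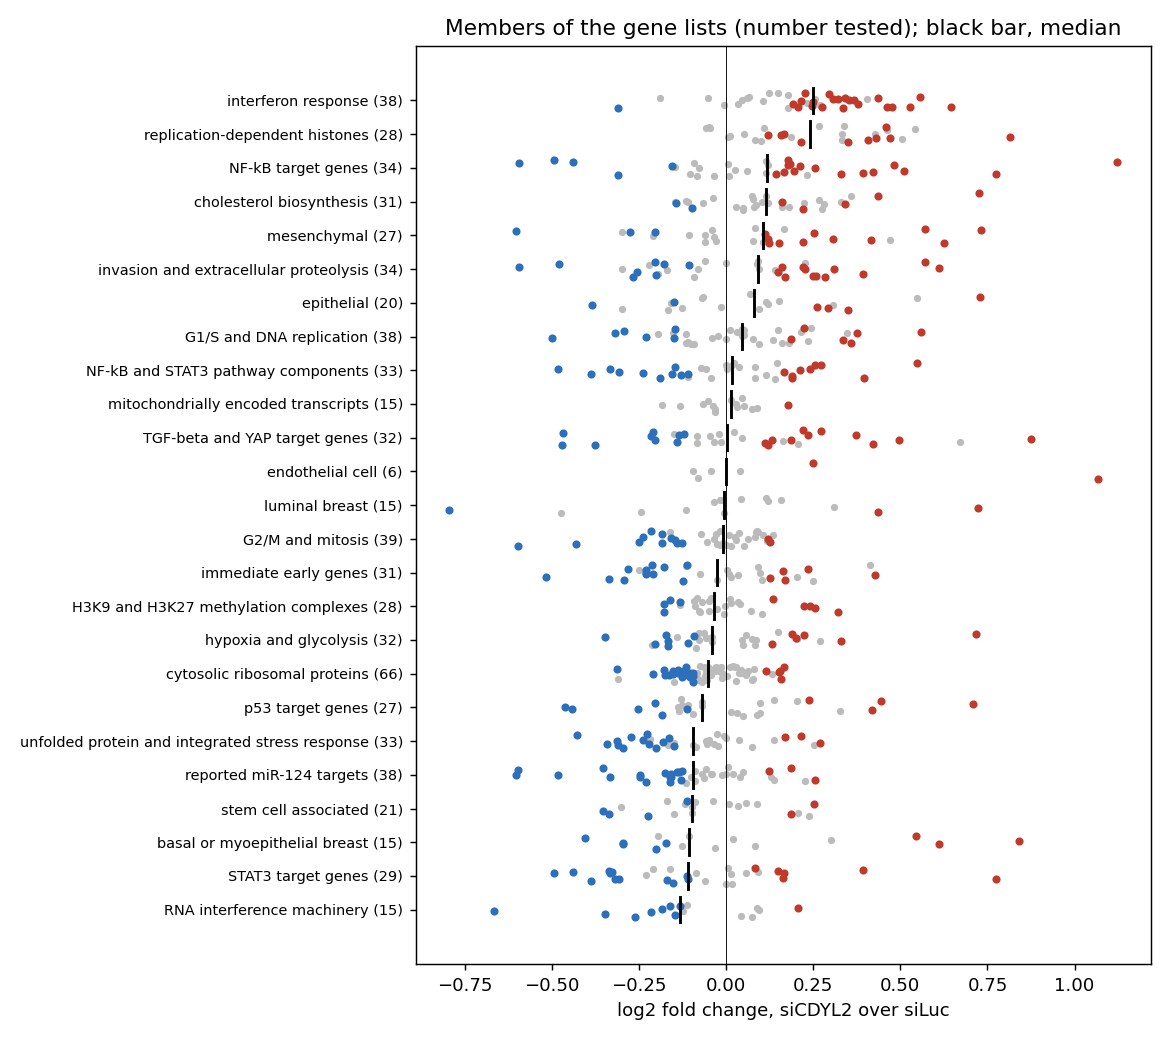
Log2 fold change (siCDYL2 over siLuc) of the members of 25 gene lists, with the number tested in brackets, red and blue dots for members that rose and fell by the edgeR test, grey dots for the rest and black bars for medians. The medians run from -0.13 for the RNA interference machinery to 0.25 for the interferon response, and most lists hold members on both sides of 0.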

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

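The number of genes changed (3865) ranged from 2571 (without siLuc replicate 1) to 4135 (without siCDYL2 replicate 3) when 1 library was left out, the number higher (1782) from 1133 to 1951, the number lower (2083) from 1438 to 2184 and the number changed at least 2-fold (79) from 67 to 105. The log2 fold change of CDYL2 stayed between -2.47 and -2.43 in all alternatives. DESeq2 called 2911 genes (2881 shared) and limma-voom 3756 (3680 shared). DESeq2 left 17 genes at 2-fold, and its independent filter gave 2390 genes no adjusted p. Without a filter on low counts 127 genes changed at least 2-fold among 31492 tested, and with the stricter filter 21 among 13213, since weakly expressed genes hold most changes of this size. Upper-quartile scaling gave 3954 genes and turned the split to 2247 higher and 1707 lower. With the replicate block 2725 genes changed (2715 shared) and 4 lists passed. The block ended the calls of 18 named genes, among them RELA (edgeR adjusted p = 0.0518) and MYC (0.0526). It also ended those of the NF-kB target, cholesterol, STAT3 target, ribosomal protein and RNA interference lists (camera adjusted p = 0.0668, 0.0668, 0.0714, 0.0714 and 0.0841) and of the families ZBTB, ZNF and RPL (0.0502, 0.0611 and 0.0966). Labels with the same number showed no closer relation than others (correlations -0.00028, -0.0788 and -0.0878). The lists past camera (9) ranged from 4 (without siLuc replicate 2 or siCDYL2 replicate 1) to 7 (without siLuc replicate 1 or 3), with 5 without siCDYL2 replicate 2, and were 0 with an estimated correlation, which widens the test for lists whose members move together. The length and GC correction, chosen after the data were seen, gave 3944 genes and 6 lists. Of 177 named genes, 145 kept their call in every setting that tested them (a few weakly expressed ones were left out of some settings), 31 lost it in at least 1, VIM gained it in 2 settings and 0 reversed. Most named genes were picked for a small p or a large change in these libraries, which favours stable calls. Of all 3865 calls, 2522 were kept in the same direction without siLuc replicate 1. Calls lost in 4 or more settings included those of ACACA, BUB1, CDH5, DUSP6, EBP, FDFT1, FOS, HIST1H2AJ, HIST2H3D, LLGL2, MIER1, NDC80, PKP3, RPL29, RPL4, STARD4 and SUZ12. The mesenchymal and the TGF-beta and YAP lists passed with fry (adjusted p = 0.0317). An unstranded column was not run, because each library holds 1 count column. Where no reason is given, the cause was not tested.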

Other observations

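The gene-family tests with their splits, the test of the interferon rise and the length and GC correction were chosen only after the results were seen, as were the genes named in the next paragraphs.

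The changed members of several gene families lay mainly in 1 direction. Families and lists share members, so their calls are not independent. The histone and ribosomal protein lists overlap the families HIST and RPL, and the interferon list also holds a PARP gene. Coding genes were grouped by the stem of their symbols, and 11 of 156 families with at least 10 tested members passed limma camera, 7 upward and 4 downward, with 0 passing with an estimated correlation (adjusted p = 0.851). The clustered protocadherin genes PCDHB, which encode adhesion proteins on chromosome 5, had 9 of 14 members rising and 0 falling (median log2 fold change 0.62, camera adjusted p = 1.93e-04, adjusted p = 0.851 with an estimated correlation). PCDHB2 rose by 0.60, PCDHB13 by 0.68 and PCDHB16 by 0.56, at a family median of 2.02 CPM, and reads shared between these near-identical genes make single members uncertain. Histone genes (HIST, 13 of 41 rising, camera adjusted p = 0.00459), collagens (COL, 11 of 27 rising and 1 falling), poly(ADP-ribose) polymerases (PARP, 7 of 12 rising) and the GALNT enzymes that start mucin-type glycans (8 of 14 rising) also passed, the last 3 at a camera adjusted p of 0.0174. COL8A1, COL4A5 and GALNT16 rose by 0.72, 0.66 and 0.64. The semaphorins (SEMA) had 7 of 15 members rising and 1 falling (camera adjusted p = 0.0289), with SEMA3A up by 0.67 and SEMA3C down by 0.36. The zinc finger genes ZNF had 69 of 444 rising and 26 falling (camera adjusted p = 0.0422), although those with the smallest p, ZNF710, ZNF335 and ZNF384, fell.

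Downward families were SEC, which act in vesicle coats and protein translocation (14 of 26 falling and 1 rising, camera adjusted p = 0.0174), the transcription factors KLF (7 of 13 falling, 0.0174) and ZBTB (13 of 36 falling and 1 rising, 0.0384), and the ribosomal proteins RPL (19 of 49 falling and 3 rising, 0.0422). Leaving out 1 library ended the calls of RPL (without siLuc replicate 2 or 3 or siCDYL2 replicate 1 or 2), ZBTB (siLuc replicate 2, siCDYL2 replicate 1 or 2), ZNF (siLuc replicate 1 or 3, siCDYL2 replicate 2 or 3), SEMA (siLuc replicate 3, siCDYL2 replicate 1), KLF (siCDYL2 replicate 2, camera adjusted p = 0.0695), and COL and GALNT (siCDYL2 replicate 3, camera adjusted p = 0.0509 and 0.0616). The RPL call also ended with upper-quartile scaling (camera adjusted p = 0.104), and RPL, ZBTB and SEMA failed with the stricter filter on low counts. The calls of PCDHB, HIST, PARP and SEC were lost with the estimated correlation alone. SEC23B, SEC24C and KLF16 fell by 0.24, 0.21 and 0.39. Apart from CDYL2, the largest ratios were in weakly expressed genes. The cystatin gene CST4 rose by 2.07 on the log2 scale and CST1 by 1.87. The stress-induced chaperone gene HSPA6 rose by 1.79 to 2.93 CPM, and COL6A3, ITGA11 and LTB rose by 1.71, 1.69 and 1.12. LINC02057 and LYPD1 fell by 1.62 and 1.45.

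The lower transcripts could reflect library composition, relief of a microRNA or off-target silencing. After the correction for length and GC content 93.3% of the lower genes were still lower, so these properties account for few of them. The miR-124 seed site ranked 135 of 210 words of the same bases by its odds ratio among lower genes. With 3' UTR length and GC content allowed for, that ratio was 1.02 (95% interval 0.895 to 1.16), so the sites do not set the lower genes apart. Before that allowance 19.6% of lower, 18.9% of higher and 16.6% of all genes not lower held a site. The listed miR-124 targets were not tested apart, so the origin of their fall is left open. Sense matches of 14 or more bases to the CDYL2 coding sequence occurred in 5.91% of lower genes and 4.16% of the others. Antisense matches of that length occurred in 4.23% and 3.78%. At 12 or more bases the sense shares were 47.2% and 37.9% and the antisense shares 41.9% and 34.3%. Transcript length was not allowed for in these shares, so the source of the excess among lower genes is open. Most falls had no sense match of 14 or more bases. The words of the CDYL2 coding sequence stood at percentile 35.7 of other coding sequences, which leaves short-seed effects of the esiRNA open.

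The interferon rise, a list median of 0.25, could be an effect of losing CDYL2 or a response to the transfected RNA itself. Cells sense double-stranded RNA, and the pools against CDYL2 and luciferase may differ in amount, length or purity. There was 1 preparation per target and no esiRNA-free sample, so these explanations cannot be separated here. A second esiRNA against another part of CDYL2 would again be transfected RNA, so a rise with it would leave both open. Rescue by a resistant CDYL2 transcript would help to separate them. With 1 preparation per target, the other changes besides that of CDYL2 have the same limit, those of NF-kB target genes included.

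The fall of the RNA interference machinery lay at percentile 0.67 of 10000 random lists matched on expression, 3' UTR length and GC content, whose 5th percentile was -0.09 against a list median of -0.13. Those properties are therefore an unlikely source of the fall, although the list call held in 4 of 15 alternative settings. It ended when any 1 library was left out and with the length and GC correction (camera adjusted p = 0.0552), upper-quartile scaling (0.0526) and the stricter filter (0.0770), while fry gave an adjusted p of 0.00249. Across settings the mean log2 fold change of the RNA interference machinery list stayed between -0.13 and -0.10. Both groups received an esiRNA pool, so competition for silencing complexes could matter here only if it differed between the pools. This was not tested.

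The 6 libraries can be divided into 3 and 3 in 10 ways, so no result can have a share below 0.05 by this test. The real grouping was the 1 of 10 with the largest value for genes changed (3865, highest other 0), genes higher (1782, 0), genes lower (2083, 0), genes changed at least 2-fold (79, 0), gene lists past camera (9, highest other 5) and gene families (11, highest other 3). Every other grouping called 0 genes changed, yet each passed 1 to 5 lists and 0 to 3 families. Camera with the preset correlation thus called lists where no single gene was called. Each other grouping sets 2 libraries of a group and 1 of the other against the reverse mix, so part of the real difference stays in it. The rest of that difference lies within the mixed groups and adds to their spread. The counts of 0 genes therefore do not show what unrelated libraries would give.

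In these libraries a large fall of CDYL2 went with small changes in many genes. Of 34 NF-kB targets 15 rose, among them ICAM1, and 5 fell, among them LIF, while STAT3 and SNAI2 were lower and FN1 was higher, so these data do not give a single direction for the pathways or for cell plasticity. A direct effect of CDYL2 on any of these genes was not tested. Effects of losing CDYL2 and of the transfected RNA itself cannot be separated here.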
